A study of Oryza sativa Japonica Group with 24 samples.

How the data were processed

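Messenger RNA libraries of rice (Oryza sativa Japonica) roots and shoots were analysed, 24 in all, from wild type (WT), a bHLH6 overexpressing line (bHLH6-OV) and an spx4 T-DNA mutant at 200 µM Pi and from WT at 10 µM Pi. Groups follow the sample labels, with 3 libraries in each of 8 groups and 12 libraries per tissue. Per the submitters' processing notes, reads were aligned with HISAT2, transcripts without annotation were assembled with StringTie, reads were counted per gene with featureCounts 1.5.0-p3, and DESeq2 was used for differential expression. The genome build is not given, and the locus names follow the style of the MSU rice annotation.

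Used here are the FPKM the authors deposited for 57668 features. They were made from reads per gene, gene length and a divisor per library. Of these features 55801 are named loci, 1682 are unannotated transcripts and 185 lie on unanchored sequence, and 22642 carry a description. FPKM multiplied by gene length was checked to fall on whole multiples of 1 step per library for 100% of features, within 0.01 reads, which gave each library's read numbers. Reads assigned to genes numbered 21.0 to 29.6 M per library. The divisor was 1.153 to 1.299 times that sum in roots and 0.733 to 1.039 times in shoots. Below that sum it is no plain library size, so FPKM may already be scaled between libraries, which TPM would undo. As the ratio differs, scaling was varied. Raw reads were not used.

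Replicates were compared in pairs by the variance of rebuilt read numbers beyond counting noise. Chi-square per degree of freedom ran from 3.65 to 137.31 and the correlation of log2(FPKM + 1) was at least 0.9851. The 2 highest values were both of WT low Pi shoot replicate 1, which was kept. Whether replicate numbers pair the libraries was checked by correlating deviations from the group means. In bHLH6-OV and spx4 roots the same-numbered pairs correlated by 0.23, 0.29 and 0.48 and unlike numbers by -0.36 to 0.19. An alternative added later treated these 2 groups as paired by number, from the values and not the labels.

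Genes with a mean FPKM of at least 1 over the 12 libraries of a tissue were tested, 22090 in roots and 19990 in shoots. A linear model of log2(FPKM + 1) with 1 mean per group was fitted to each tissue with limma 3.58.1 (robust empirical Bayes with a trend) in R 4.3.3. Each tissue had 4 comparisons: bHLH6-OV against WT, spx4 against WT, WT low against high Pi, and spx4 against bHLH6-OV. Differences of effect between root and shoot were tested in 3 comparisons over all 24 libraries and 22980 genes. p-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 made a call. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 and drawn with matplotlib 3.10.9. Folds against a group at 0 reads are lower bounds against a floor of 3 reads in each library of the group.

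Gene lists were tested with limma's camera, with the preset correlation of 0.01 and with an estimated correlation, and by adjusting over the list alone. Before the data were examined, lists were fixed for Pi starvation markers, Pi signalling regulators, PHT1 transporters, jasmonate, phytoalexins, iron, nitrogen, defence and root tissue markers by gene. Others were fixed by words in descriptions: purple acid phosphatases, membrane lipid remodelling, lipoxygenases, photosynthesis, heat shock proteins, cytosolic ribosomal proteins, class III peroxidases and aquaporins. Lists for JAZ repressors, chitinases, expansins, phenylalanine ammonia-lyase and lignin, and SPX proteins by word matched no description. Zim domain proteins, SPX domain proteins, chitinases by enzyme family, ribosomal proteins and WRKY factors were added after the data were examined, which made 22 lists. The values carry no gene symbols, so the locus of each of 113 symbols was taken from published assignments known to the analyst and then checked. Of these, 112 were kept, 104 had a description that fits the family, 8 had none, and 67 lay within 0.3 Mb of the gene of that symbol in the reference gene table, after the shift of neighbouring genes. By that rule 6 did not (PT10, VPE1, PHO1-1, NAAT1, NPR1 and LSI6), though without the shift all but VPE1 did, and 39 had no such gene on the chromosome. A list of 2 genes (membrane lipid remodelling) was not given to camera.

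Genes named in the report follow rules. bHLH6 and SPX4 come first. Next come the 10 highest and 10 lowest log2 fold changes among calls with non-overlapping replicates, a mean FPKM of at least 5 in 1 group and a symbol or description, where genes with a domain name only are counted. From each list come members of large fold change, and members whose call ended when 1 library was left out are mostly not named. Lists share members, so their tests are not independent. The Pi starvation markers share 5 genes with the PHT1 transporters, 6 with the SPX domain proteins, 2 with the purple acid phosphatases and 1 with membrane lipid remodelling. The SPX domain proteins share 5 with the Pi signalling regulators, and the defence markers share WRKY45, WRKY62 and WRKY76 with the WRKY factors. The root tissue markers share IRT1 with iron, NAR2.1 with nitrogen and 2 genes with aquaporins.

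The analysis was tested on simulated data with 200 changed genes per comparison. In roots 56.7 to 65.7% of genes changed 1.5-fold, 92.5 to 95.5% of those changed 2-fold and 98.5 to 100% of those changed 4-fold were recovered, with 11 false calls each. In shoots these were 11.9 to 20.9%, 76.1 to 82.1% and 98.5 to 100%, with 6 to 15 false calls. For differences between root and shoot they were 3 to 9%, 49.3 to 65.7% and 92.4 to 93.9%, with 3 to 8 false calls.

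Alternatives fixed before the data were examined were other pseudocounts (0.1 and 0.5), no filter and a filter of 5, quantile normalization, median ratio scaling, TPM, a fit of only the 6 libraries compared, ordinary empirical Bayes, arrayWeights, the replicate number as a block, each library compared left out, a 2-fold minimum, and voom on rebuilt reads. Added afterwards were the shoot comparisons without WT low Pi shoot replicate 1 and spx4 against WT without genes on in 1 group and off in the other. Also added were a replicate block in spx4 and bHLH6-OV roots only and list tests without bHLH6 and SPX4. Shared calls were set against the product of the 2 counts over genes tested. They were also set against 100 draws in which unchanged groups and the WT libraries they share were all simulated.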

Results

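Messenger RNA was sequenced from the roots and shoots of rice (Oryza sativa Japonica) seedlings in 8 groups of 3 libraries, 24 libraries in all. Wild type (WT), a line overexpressing the transcription factor bHLH6 (bHLH6-OV) and a T-DNA insertion mutant of the SPX4 gene (spx4) were supplied with 200 µM phosphate (Pi; high Pi), and WT was also supplied with 10 µM Pi (low Pi). Supply began when the seedlings were 7 days old and lasted 2 weeks, and each library came from 3 pooled seedlings. Each library held 21.0 to 29.6 M reads assigned to genes. Levels are FPKM (fragments per kilobase of transcript, scaled per library), as mean ± SD over the 3 libraries of a group. Log2 fold changes are of FPKM + 1. Calls are genes with an adjusted p under 0.05 in limma.

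The manipulated genes were read first in every group. The bHLH6 gene (LOC_Os04g23550, also known as the jasmonate-responsive gene RERJ1) stood at 134 ± 25.6 FPKM in bHLH6-OV roots and 4.75 ± 1.32 in WT roots (SD, n = 3). It stood at 105 ± 17.5 in bHLH6-OV shoots and 5.24 ± 0.0435 in WT shoots (SD, n = 3). It was called higher in the overexpressing line in both tissues (limma adjusted p = 0.00076 in roots and 0.00075 in shoots). In spx4 it stood at 3.78 ± 3.72 FPKM in roots and 23 ± 9.23 in shoots (SD, n = 3). Neither was called (limma adjusted p = 0.838 and 0.178, log2 fold change 1.87 in shoots, higher in 3 of 3 shoot libraries). In WT at low Pi it stood at 8.48 ± 8.04 FPKM in roots (not called, limma adjusted p = 0.749) and at 55.4 ± 40.2 in shoots (SD, n = 3, called higher, limma adjusted p = 0.00484). Of these shoots, replicate 1 held 9.25 FPKM and replicates 2 and 3 held 83.1 and 73.8. Without WT low Pi shoot replicate 1, the higher level of bHLH6 in spx4 shoots passed the test. SPX4 (LOC_Os03g61200), whose protein binds the transcription factor PHR2 when Pi is ample, was lower in spx4 but far from absent. It stood at 6.21 ± 0.863 FPKM against 11.3 ± 0.193 in WT roots and 7.67 ± 0.89 against 13.8 ± 1.61 in WT shoots (SD, n = 3, limma adjusted p = 0.00101 and 0.0035). Its level was 11 ± 1.39 FPKM in bHLH6-OV roots and 10.1 ± 0.574 in WT roots at low Pi, and 12.3 ± 0.847 in WT shoots at low Pi (SD, n = 3), none of them called. In bHLH6-OV shoots SPX4 stood at 10.2 ± 1.38 FPKM (SD, n = 3, log2 fold change -0.4, limma adjusted p = 0.022), a call that ended with TPM scaling and without WT shoot replicate 3 or bHLH6-OV shoot replicate 1 or 3.

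**Figure D1:**
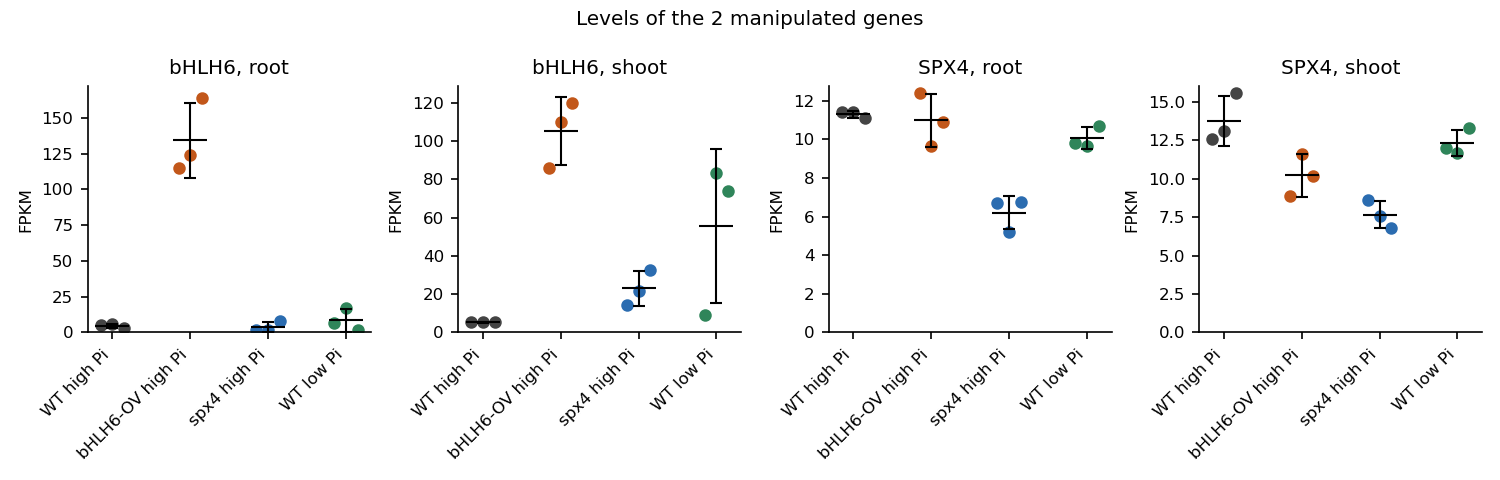
FPKM of bHLH6 and SPX4 in each library of the 4 groups of each tissue, with the mean and SD over 3 libraries as bars. bHLH6 is highest in the overexpressing line and varies widely between the shoot libraries of WT at low Pi; SPX4 is lowest in spx4.

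Tissue separated the libraries most, with 86.9% of the variance of log2(FPKM + 1) on the first principal component over all 24 libraries. Within roots the first component held 53.9% and set the low Pi libraries apart from the rest, and the second (18.1%) set bHLH6-OV and low Pi apart from WT and spx4. Within shoots the first component (45.4%) again set low Pi apart and the second (30.5%) held bHLH6-OV at one end. The spx4 libraries lay near WT on both components in shoots and on the second in roots, and on the first in roots between WT and bHLH6-OV. WT low Pi shoot replicate 1 stood apart from replicates 2 and 3, with 375 genes at least 2-fold higher and 678 at least 2-fold lower than their mean, against 163 genes at least 2-fold apart between replicates 2 and 3. Photosynthesis genes were lower in that library, 19 of 26 by at least 2-fold.

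**Figure D2:**
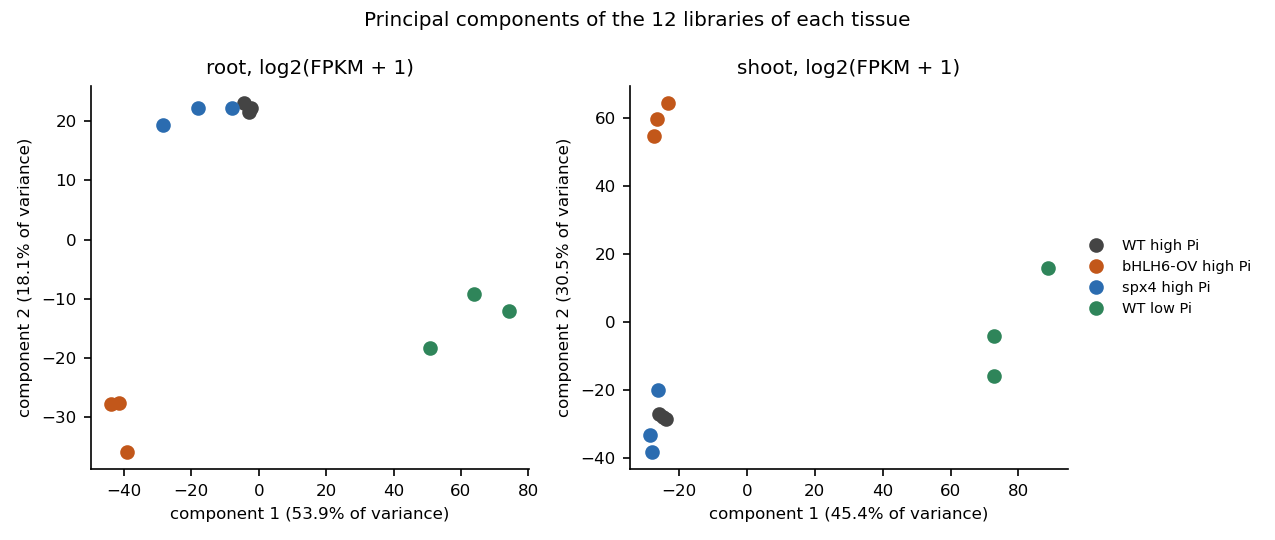
The 12 root libraries (left) and the 12 shoot libraries (right) on the first 2 principal components of log2(FPKM + 1), with the percent of variance on each axis. Low Pi libraries sit at one end of the first component in both tissues, and bHLH6-OV shoots at one end of the second.

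bHLH6-OV roots were set against WT at high Pi. With no other line, line effects cannot be told from those of bHLH6. The largest falls included iron uptake genes. The nicotianamine synthases NAS2 and NAS1, which make the precursor of the iron-chelating phytosiderophores, fell from 777 ± 274 to 20.7 ± 11.1 FPKM and from 599 ± 211 to 16.9 ± 8.77 (SD, n = 3, limma adjusted p = 0.000295 and 0.000243). The iron-phytosiderophore transporter YSL15 fell from 148 ± 27.6 to 5.11 ± 2.49 FPKM and the phytosiderophore exporter TOM1 from 145 ± 42.4 to 8.93 ± 4.43 (SD, n = 3, limma adjusted p = 0.000115 for both). NAAT1 and DMAS1, enzymes of the same pathway, and the metal transporter NRAMP1 fell with log2 fold changes of -3.78, -3.15 and -3.19. NAS1 and NAS2 are close copies, as are the ferritins FER1 and FER2 and the Pi transporters PT9 and PT10, so the division of reads within each pair is uncertain.

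Of 16 tested genes of the iron homeostasis list 11 were called lower and 4 higher, and the 4 higher were the ferritins FER1 and FER2, the vacuolar iron transporter VIT2 and the iron-sensing ubiquitin ligase HRZ2. Adjusted over the list alone, 12 were lower and 4 higher, and limma's camera placed the list low (adjusted p = 3.7e-05, and adjusted p = 0.516 with an estimated correlation). A metallothionein (LOC_Os12g38270) fell from 472 ± 138 to 36 ± 15.8 FPKM, a zinc/iron permease (LOC_Os03g46454) from 11.4 ± 3.66 to 0.42 ± 0.27, and an oligopeptide transporter (LOC_Os01g65110) from 12.9 ± 3.41 to 0.64 ± 0.177 (SD, n = 3, limma adjusted p = 2.72e-05, 0.000785 and 1.98e-05). Of the Pi transporters, 4 of 8 tested PHT1 genes were called higher, 0 lower and 4 not called, as many as adjusted over the list alone (limma camera adjusted p = 0.00132, and 0.516 with an estimated correlation). PT2, a low-affinity transporter, rose from 18.3 ± 0.222 to 86.7 ± 12.8 FPKM (SD, n = 3, limma adjusted p = 2.47e-06), and PT3 from 0.145 ± 0.0177 to 1.53 ± 0.0434. The call of PT10 ended without WT root replicate 1, 2 or 3 or bHLH6-OV root replicate 3. The Pi starvation markers as a whole were mixed, with 4 higher, 5 lower and 10 not called (5 and 5 adjusted over the list alone, limma camera adjusted p = 0.764). SPX2, a nuclear SPX protein, fell from 5.68 ± 0.938 to 0.0504 ± 0.0526 FPKM (SD, n = 3, limma adjusted p = 1.39e-06). Of the Pi signalling regulators 4 of 12 were higher, bHLH6 itself included and the SPX-domain transporter SPX-MFS3 next (log2 fold change 1.2). They had 5 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 0.0199, and 0.685 with an estimated correlation), and without bHLH6 and SPX4 the list did not pass (limma camera adjusted p = 0.0511).

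Photosynthesis genes, used as markers of shoot tissue in roots, were called higher in 16 of 22 cases and lower in 0. The photosynthesis genes had 17 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 5.25e-08, and 0.516 with an estimated correlation). LOC_Os12g19381 of this list rose from 24 ± 3.4 to 94.4 ± 14.6 FPKM (SD, n = 3, limma adjusted p = 0.00716). Lists of WRKY transcription factors, Zim domain proteins, SPX domain proteins, chitinases and ribosomal proteins were added after the data were examined. Of WRKY factors 19 of 68 were higher and 1 lower, with LOC_Os05g50700 at 4.33 ± 1.04 against 0.314 ± 0.0895 FPKM (SD, n = 3). The WRKY factors had 21 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 1.27e-06, and 0.516 with an estimated correlation). The root tissue markers gave 0 higher and 2 lower of 9, the iron transporter IRT1 (log2 fold change -2.64) and RCc3 (from 2250 ± 104 to 1290 ± 153 FPKM; SD, n = 3). The remaining lists passed no camera test, with adjusted p from 0.0511 (JAZ repressors and other Zim domain proteins) to 0.893 (the 5 proteins annotated as cytosolic ribosomal). Among them, the aquaporin list lacks the genes described as major intrinsic proteins. In jasmonate biosynthesis and signalling, 0 of 8 genes were called, and AOC, an enzyme of jasmonate synthesis, stood at 76.8 ± 26.8 against 69.9 ± 2.5 FPKM (SD, n = 3, limma adjusted p = 0.827).

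Of the most strongly raised genes, 2 named here were silent in WT. A Harbinger transposase-derived gene (LOC_Os12g12500) was at 0 reads in all 3 WT root libraries and at least 103-fold higher in bHLH6-OV, and a transposase gene (LOC_Os10g20280) at least 161-fold higher, each against a floor of 3 reads over the group. A transferase (LOC_Os01g15740) rose from 0.011 ± 0.0191 to 12.9 ± 1.14 FPKM and a wall-associated receptor kinase (LOC_Os07g14470) from 0.471 ± 0.328 to 13.3 ± 3.23 (SD, n = 3, limma adjusted p = 2.65e-11 and 7.72e-07). A further 5 genes of the 10 most raised carry a domain name only. In each gene chosen by size here and below, the 3 libraries of one group lay outside the range of the other 3, which chance gives in 10% of genes. Over the transcriptome, 3975 of 22090 root genes were called by limma, 1684 higher and 2291 lower, and 646 of them changed at least 2-fold. The count was 2568, 2350 and 2156 without WT root replicate 1, 2 and 3.

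Roots of the spx4 line, which still held SPX4 RNA, were set against WT at ample Pi. The iron uptake genes were again the list that moved most. TOM1 fell from 145 ± 42.4 to 14.6 ± 7.5 FPKM and YSL15 from 148 ± 27.6 to 19.6 ± 16.2 (SD, n = 3, limma adjusted p = 0.000728 and 0.00442). NAAT1 and NRAMP1 fell with log2 fold changes of -2.83 and -2.47. NAS2 and NAS1 stood at 79.3 ± 70.3 and 64 ± 55.2 FPKM (SD, n = 3, limma adjusted p = 0.0107 and 0.00895). The first call ended without WT root replicate 1 or spx4 root replicate 1 or 2, the second without WT root replicate 1. Of the 16 iron genes 11 were called lower and 1 higher, the ferritin FER2. The iron genes had 3 higher and 12 lower adjusted over the list alone (limma camera adjusted p = 5.56e-10, and 0.235 with an estimated correlation). The metallothionein LOC_Os12g38270 fell from 472 ± 138 to 46.5 ± 4.03 FPKM (SD, n = 3, limma adjusted p = 0.000106).

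IPS1, a non-coding RNA raised when Pi is short, rose from 1.47 ± 0.685 to 7.89 ± 1.48 FPKM (SD, n = 3, limma adjusted p = 5.15e-05). With it, 3 of the 19 Pi starvation markers were higher and 0 lower. The Pi starvation markers had 4 higher and 0 lower adjusted over the list alone (limma camera adjusted p = 0.000781, and 0.68 with an estimated correlation). PT2 stood at 32.5 ± 2.15 against 18.3 ± 0.222 FPKM and PT3 at 0.583 ± 0.13 against 0.145 ± 0.0177 (SD, n = 3, limma adjusted p = 0.0132 and 0.0409), which made 2 of 8 PHT1 genes higher. The PHT1 transporters had 2 higher and 0 lower adjusted over the list alone (limma camera adjusted p = 0.0246, and 0.68 with an estimated correlation). The call of PT2 ended without WT root replicate 1, 2 or 3 or spx4 root replicate 2, and that of PT3 also without spx4 root replicate 3. Nitrogen uptake and assimilation had 1 of 15 genes lower, the nitrate reductase NIA1 (25.2 ± 1.8 to 15 ± 0.788 FPKM; SD, n = 3, limma adjusted p = 0.0031). It had 5 lower adjusted over the list alone (limma camera adjusted p = 0.000781, and 0.68 with an estimated correlation). The camera test also placed the photosynthesis genes high (1 of 22 called, 1 adjusted over the list alone, limma adjusted p = 6.19e-07, and adjusted p = 0.68 with an estimated correlation). It placed the root tissue markers low (IRT1 alone called, 1 of 9, also adjusted over the list alone, limma adjusted p = 0.0246, and adjusted p = 0.68 with an estimated correlation). The call in the photosynthesis list, LOC_Os12g19470 (12.7 ± 5.85 against 4.92 ± 0.765 FPKM; SD, n = 3), ended without WT root replicate 1, 2 or 3 or spx4 root replicate 1 or 2. The other lists passed no camera test, and 0 of 18 purple acid phosphatases and 0 of 206 ribosomal proteins were called by limma, where over all genes 2910 had an unadjusted p under 0.05.

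Many of the largest changes outside the lists were near on or off. A gene annotated as EARLY FLOWERING 4, a circadian clock component (LOC_Os08g27870), stood at 66.7 ± 1.15 FPKM in spx4 and 0.0189 ± 0.0328 in WT roots, and a nitrite/sulphite reductase gene (LOC_Os02g52730) at 88.7 ± 7.66 against 0.745 ± 0.351 (SD, n = 3, limma adjusted p = 7.04e-13 and 3.96e-07). A MutS mismatch repair gene (LOC_Os07g30240) and the transferase LOC_Os01g15740 rose with log2 fold changes of 3.6 and 3.73, and an amino acid transporter (LOC_Os04g12499) with 2.66. A subtilase-type peptidase gene at the start of chromosome 4 (LOC_Os04g03796, from 1702003 to 1710519) fell from 45.7 ± 8.85 to 0.00991 ± 0.0116 FPKM and a legume lectin gene (LOC_Os04g03579) from 233 ± 9.5 to 14.3 ± 1.38 (SD, n = 3, limma adjusted p = 1.07e-09 and 3.5e-10). A Pif1-like helicase (LOC_Os04g04390) fell too (log2 fold change -3.48). The call of a carboxyl methyltransferase (LOC_Os11g15300; log2 fold change 1.58) ended without WT root replicate 1 or spx4 root replicate 1 or 2, and 5 of the 20 genes chosen by size carry a domain name only. Calls numbered 543 of 22090 genes in limma, 140 higher and 403 lower, with 227 changed at least 2-fold. The count was 343, 342 and 331 without WT root replicate 1, 2 and 3 and 344 without spx4 root replicate 2, and 428 without the genes on in one group and off in the other.

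The response of WT roots to Pi shortage was read from low against high Pi. All 19 Pi starvation markers rose (19 adjusted over the list alone, limma camera adjusted p = 1.56e-31), and this list passed also with an estimated correlation (adjusted p = 0.0343). IPS1 rose from 1.47 ± 0.685 to 1590 ± 179 FPKM, and the SPX genes SPX6 and SPX5 from 1.12 ± 0.118 to 167 ± 45.3 and from 2.14 ± 0.505 to 181 ± 39.7 (SD, n = 3, limma adjusted p = 3.4e-11, 8.11e-10 and 8.11e-10). The Pi transporters PT3, PT6 and PT10 rose with log2 fold changes of 5.42, 4.73 and 4.25, and the phosphatase PECP1 from 7.67 ± 1.46 to 205 ± 11.9 FPKM (SD, n = 3). Over the PHT1 family 7 of 8 genes were higher, and PT1 alone was not called, at 77.9 against 81.4 FPKM. The PHT1 transporters had 7 higher and 0 lower adjusted over the list alone (limma camera adjusted p = 7.06e-10, and 0.081 with an estimated correlation). A diacylglycerol glucosyltransferase gene (LOC_Os08g20420) of the kind that makes glycolipids rose from 0.279 ± 0.0895 to 56.1 ± 7.22 FPKM, a lipase gene (LOC_Os11g43760) from 0.0187 ± 0.00105 to 25.8 ± 1.97 and a phosphoesterase gene (LOC_Os10g02750) from 1.15 ± 0.197 to 62.5 ± 6.74 (SD, n = 3, limma adjusted p = 3.4e-11, 3.01e-11 and 1.93e-09).

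Purple acid phosphatases, enzymes that release Pi from organic compounds, were higher in 10 and lower in 2 of 18 cases, with PAP10a at 143 ± 21.9 against 8.23 ± 0.891 FPKM (SD, n = 3). The acid phosphatases had 10 higher and 2 lower adjusted over the list alone (limma camera adjusted p = 4.42e-06, and 0.081 with an estimated correlation). SPX domain proteins were higher in 8 of 9 cases, and both members of the membrane lipid remodelling list rose, GDPD2 from 49.9 ± 3.52 to 309 ± 24.2 FPKM (SD, n = 3). The SPX domain proteins had 8 higher and 0 lower adjusted over the list alone (limma camera adjusted p = 2.9e-09, and 0.081 with an estimated correlation). The Pi signalling regulators were split, 3 higher, 5 lower and 4 not called (3 and 6 adjusted over the list alone, limma camera adjusted p = 0.14). PHR4 rose (log2 fold change 1.33), while the MYB factor RLI1 fell from 44.2 ± 2.92 to 6.04 ± 2.24 FPKM (SD, n = 3). The ubiquitination factors NLA1 and PHO2, which lower Pi transporter levels, fell with log2 fold changes of -1.23 and -1.22.

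Genes for nitrogen and iron uptake mostly fell. In nitrogen uptake and assimilation 13 of 15 genes were lower and 0 higher. The nitrogen genes had 0 higher and 13 lower adjusted over the list alone (limma camera adjusted p = 4.56e-12, and 0.081 with an estimated correlation). The nitrate transporter NRT1.1B fell from 50.3 ± 7.02 to 2.62 ± 0.373 FPKM, NIA1 from 25.2 ± 1.8 to 1.85 ± 0.465, and the glutamine synthetase GS1-2 from 434 ± 66.5 to 50.1 ± 12.7 (SD, n = 3, limma adjusted p = 4.14e-09, 3.24e-09 and 6.32e-06). Of the 16 iron genes 13 were lower and 2 higher. The iron genes had 3 higher and 13 lower adjusted over the list alone (limma camera adjusted p = 1.33e-08, and 0.081 with an estimated correlation). YSL15 fell from 148 ± 27.6 to 1.47 ± 1.07 FPKM, NAS2 from 777 ± 274 to 30.4 ± 17.1 and TOM1 from 145 ± 42.4 to 6.14 ± 2.52 (SD, n = 3, limma adjusted p = 6.85e-06, 0.000242 and 2.1e-05). A cytochrome P450 (LOC_Os06g43410) and a molybdopterin-binding oxidoreductase (LOC_Os02g53130) fell with log2 fold changes of -4.85 and -4.13, and 1 of the 20 genes chosen by size carries a domain name only.

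Photosynthesis genes were lower in 16 and higher in 2 of 22 cases in low Pi roots, the opposite of bHLH6-OV roots. The photosynthesis genes had 2 higher and 18 lower adjusted over the list alone (limma camera adjusted p = 5.31e-07, and 0.329 with an estimated correlation). The root tissue markers were lower in 5 of 9 cases, led by IRT1 and the nitrate transport partner NAR2.1 (log2 fold changes -3.28 and -2.86), and the call of the silicon channel LSI1 ended without WT root replicate 3. The root tissue markers had 0 higher and 6 lower adjusted over the list alone (limma camera adjusted p = 0.000538, and 0.124 with an estimated correlation). Lipoxygenases, which start jasmonate synthesis, were higher in 7 and lower in 1 of 11 cases, with LOC_Os03g52860 at 339 ± 53.2 against 148 ± 14 FPKM (SD, n = 3). The lipoxygenases had 8 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 0.00844, and 0.329 with an estimated correlation). Camera also passed the WRKY factors (9 higher and 24 lower of 68, 9 and 26 adjusted over the list alone, limma adjusted p = 0.0196, and adjusted p = 0.596 with an estimated correlation). It also passed the defence markers (0 and 4 of 7, also adjusted over the list alone, limma adjusted p = 0.0441, and adjusted p = 0.409 with an estimated correlation) and the phytoalexin genes (2 and 0 of 5, 4 and 0 adjusted over the list alone, limma adjusted p = 0.0451, and adjusted p = 0.409 with an estimated correlation). The defence list includes WRKY76 and WRKY62 (log2 fold changes -0.88 and -0.87), and the phytoalexin list CPS4 and KSL8, which make diterpene skeletons (0.94 and 0.64). Low Pi changed 6941 of 22090 root genes in limma, 3380 higher and 3561 lower, with 1182 changed at least 2-fold.

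The lines were also compared with each other, which leaves WT out. bHLH6 and SPX4 were both lower in spx4 roots than in bHLH6-OV roots (log2 fold changes -5.07 and -0.74, limma adjusted p = 0.000434 and 0.000979). In roots, spx4 held more IPS1 than bHLH6-OV (7.89 ± 1.48 against 0.347 ± 0.0286 FPKM), more SPX2 (3.98 ± 0.28 against 0.0504 ± 0.0526) and less PT2 (32.5 ± 2.15 against 86.7 ± 12.8; SD, n = 3, limma adjusted p = 8.51e-07, 4.63e-06 and 0.000106). Of the Pi starvation markers 4 were higher and 2 lower of 19 (6 and 3 adjusted over the list alone, limma camera adjusted p = 0.22), and of the PHT1 genes 2 were lower of 8. The PHT1 transporters had 0 higher and 3 lower adjusted over the list alone (limma camera adjusted p = 0.00687, and 0.67 with an estimated correlation). Of the iron genes 1 was higher (IRT1, log2 fold change 0.71), 2 were lower (VIT2 and FER2, -0.68 and -0.46) and 13 were not called (5 higher and 3 lower adjusted over the list alone, list median 0.56, limma camera adjusted p = 0.362). The call of VIT2 ended without bHLH6-OV root replicate 2 or 3 or spx4 root replicate 1 or 3, and that of FER2 without bHLH6-OV root replicate 2 or spx4 root replicate 3. WRKY factors were lower in spx4 in 9 of 68 cases and higher in 0, with LOC_Os05g50700 at 0.442 ± 0.0591 against 4.33 ± 1.04 FPKM (SD, n = 3). The WRKY factors had 0 higher and 11 lower adjusted over the list alone (limma camera adjusted p = 1.67e-05, and 0.67 with an estimated correlation). The Pi signalling regulators had 3 lower of 12, of which 2 are bHLH6 and SPX4 themselves. Camera passed the list with these 2 genes (3 lower adjusted over the list alone, limma adjusted p = 0.00934, and adjusted p = 0.67 with an estimated correlation) but not without them (limma adjusted p = 0.158). Camera placed low the photosynthesis genes (0 of 22 called, also adjusted over the list alone, limma adjusted p = 0.0016, and adjusted p = 0.857 with an estimated correlation) and the Zim domain proteins (1 lower of 14, also adjusted over the list alone, limma adjusted p = 0.0453, and adjusted p = 0.857 with an estimated correlation). Beyond the on or off genes already named, spx4 held less of a papain-type peptidase (LOC_Os04g13140, 0.513 ± 0.151 against 26.4 ± 1.34 FPKM) and more of a class III peroxidase (LOC_Os05g04410, 50.7 ± 10.4 against 14.3 ± 0.974; SD, n = 3, limma adjusted p = 1.35e-08 and 1.23e-05). A NADH:flavin oxidoreductase (LOC_Os06g11240) and a terpene synthase (LOC_Os04g27190) were higher in spx4 with log2 fold changes of 3.01 and 1.96. A block by replicate number was chosen from these values. With it jasmonate genes passed camera as lower in spx4 (2 lower of 8, 3 adjusted over the list alone, limma adjusted p = 0.0186). Without the block 0 were called, also over the list alone (limma camera adjusted p = 0.172), and with an estimated correlation the blocked list did not pass (adjusted p = 0.532). The block also gave 3 higher and 3 lower iron genes, 6 lower Zim domain proteins and 2 lower photosynthesis genes. In all, limma called 1454 of 22090 genes, 690 higher and 764 lower in spx4, with 815 and 906 called without spx4 root replicate 2 and 3.

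In shoots, bHLH6-OV raised defence markers and phytoalexin genes, of which 0 of 7 and 0 of 5 tested were called higher in its roots. The pathogenesis-related gene PR1b rose from 5.17 ± 4.52 to 417 ± 85.6 FPKM and PR10a from 22.5 ± 10.1 to 584 ± 112 (SD, n = 3, limma adjusted p = 0.000131 and 0.000231). All 12 tested genes of diterpenoid phytoalexin synthesis were higher. They include the cytochrome P450 CYP701A8 (0.924 ± 0.129 to 53.5 ± 19.6 FPKM) and the copalyl diphosphate synthases CPS2 (0.296 ± 0.0606 to 33.6 ± 19.2) and CPS4 (0.767 ± 0.149 to 28.5 ± 5.85; SD, n = 3, limma adjusted p = 5.28e-06, 0.000125 and 2.66e-05). The phytoalexin genes had 12 higher and 0 lower adjusted over the list alone (limma camera adjusted p = 2.07e-11, and 0.235 with an estimated correlation). A terpene synthase gene outside that list (LOC_Os08g07080) rose from 13.5 ± 15.7 to 341 ± 54.1 FPKM (SD, n = 3, limma adjusted p = 0.00118).

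Of the 8 defence markers 7 were higher and 0 lower, and NPR1, a salicylic acid receptor, was not called, at 9.97 against 10 FPKM. The defence markers had 7 higher and 0 lower adjusted over the list alone (limma camera adjusted p = 9.45e-07, and 0.235 with an estimated correlation). The Bet v I family genes LOC_Os12g36850 and LOC_Os12g36860 beside PR10a rose with log2 fold changes of 4.62 and 4.45. Chitinases were higher in 8 and lower in 1 of 18 cases, with the family 19 gene LOC_Os10g39680 at 163 ± 109 against 3.14 ± 1.52 FPKM (SD, n = 3, limma adjusted p = 0.000109). The chitinases had 9 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 0.000243, and 0.29 with an estimated correlation). WRKY factors were higher in 26 and lower in 14 of 61 cases, with LOC_Os01g40260 at 21.4 ± 0.414 against 0.699 ± 0.352 FPKM (SD, n = 3). The WRKY factors had 27 higher and 14 lower adjusted over the list alone (limma camera adjusted p = 0.047, and 0.372 with an estimated correlation). The jasmonate list passed no camera test (adjusted p = 0.531), with 1 higher and 3 lower of 8 genes (1 and 3 adjusted over the list alone) and a median of -0.05 that became 0.17 with TPM. The allene oxide synthase AOS2, an enzyme of jasmonate synthesis, fell from 16.4 ± 1.63 to 3.3 ± 1.24 FPKM (SD, n = 3, limma adjusted p = 0.000147).

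Some iron genes moved in shoots as well. NRAMP1 fell from 86.6 ± 22.8 to 0.442 ± 0.12 FPKM and the iron-deficiency regulator IRO2 from 23.3 ± 4.49 to 0.0335 ± 0.0436 (SD, n = 3, limma adjusted p = 7.36e-06 and 1.9e-08). The ferritins FER1 and FER2 rose from 30.3 ± 1.99 to 113 ± 25.8 FPKM and from 22.9 ± 3.93 to 79.7 ± 17.1 (SD, n = 3, limma adjusted p = 0.000655 and 0.00102). Over the list 2 were higher and 5 lower of 11. The iron genes had 2 higher and 5 lower adjusted over the list alone (limma camera adjusted p = 0.047, and 0.29 with an estimated correlation). Pi starvation markers were lower in 6 and higher in 2 of 14 cases. SPX2 fell from 11.2 ± 0.598 to 0.793 ± 0.229 FPKM and SPX-MFS2 from 47 ± 5.42 to 14.6 ± 1.09 (SD, n = 3, limma adjusted p = 1.1e-07 and 1.34e-05). The Pi starvation markers had 2 higher and 6 lower adjusted over the list alone (limma camera adjusted p = 0.0375, and 0.526 with an estimated correlation). SPX domain proteins were lower in 4 of 11 cases. The SPX domain proteins had 0 higher and 4 lower adjusted over the list alone (limma camera adjusted p = 0.047, and 0.571 with an estimated correlation), and without SPX4 the list did not pass (limma camera adjusted p = 0.0742). The Pi transporter PT8 rose from 29.6 ± 2.93 to 68.7 ± 11.8 FPKM (SD, n = 3, limma adjusted p = 0.00434), 1 of 3 PHT1 genes tested (limma camera adjusted p = 0.796; median -0.12, and 0.1 with TPM). In the nitrogen list the asparagine synthetase ASN1 fell from 23 ± 5.78 to 1.31 ± 0.832 FPKM (SD, n = 3, limma adjusted p = 4.82e-06). That list had 2 higher and 5 lower of 12 (2 and 5 adjusted over the list alone, limma camera adjusted p = 0.531).

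Ribosomal proteins were higher in 60 and lower in 6 of 207 cases in bHLH6-OV shoots, and of the 5 annotated as cytosolic 3 were higher. The ribosomal proteins had 60 higher and 6 lower adjusted over the list alone (limma camera adjusted p = 4.73e-06, and 0.628 with an estimated correlation). The cytosolic ribosomal proteins had 4 higher and 0 lower adjusted over the list alone (limma camera adjusted p = 0.047, and 0.571 with an estimated correlation). LOC_Os03g63950, a ribosomal protein gene that fell, went from 821 ± 109 to 385 ± 96.9 FPKM, and LOC_Os02g01332, which rose, from 20.3 ± 1.23 to 40.2 ± 2.32 (SD, n = 3, limma adjusted p = 0.00741 and 0.000359). The heat shock protein LOC_Os09g28354 rose from 3.04 ± 0.197 to 33.8 ± 4.05 FPKM (SD, n = 3). Its list had 12 higher and 5 lower of 69 (11 and 5 adjusted over the list alone, limma camera adjusted p = 0.298). Aquaporins gave 3 higher and 1 lower of 11 (3 and 1 adjusted over the list alone, limma camera adjusted p = 0.0633). Class III peroxidases gave 10 and 12 of 55 (10 and 12 adjusted over the list alone, limma camera adjusted p = 0.971; median -0.11, and 0.09 with TPM). Among the lowest genes were an aminotransferase (LOC_Os01g09700, 54.4 ± 3.06 to 3.39 ± 0.687 FPKM), a family 1 glycoside hydrolase (LOC_Os01g59840, 21.3 ± 1.79 to 0.949 ± 0.191) and a carboxyl methyltransferase (LOC_Os11g15040, 163 ± 30.9 to 17.2 ± 9.2; SD, n = 3, limma adjusted p = 1.28e-06, 7.34e-07 and 3.06e-05). Of the 20 genes chosen by size 6 carry a domain name only. In all, limma called 6266 of 19990 genes, 2801 higher and 3465 lower (44.7% higher), with 1463 changed at least 2-fold. The higher share was 56.4% with median ratio scaling and 75.4% with TPM, which moved the median log2 fold change of all genes from -0.05 to 0.15.

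In shoots of spx4 the iron genes were the one list past the camera test. NRAMP1 fell from 86.6 ± 22.8 to 10 ± 9.16 FPKM and IRO2 from 23.3 ± 4.49 to 3.53 ± 1.15 (SD, n = 3, limma adjusted p = 0.00247 and 8.63e-06). Of 11 iron genes 3 were lower and 0 higher. The iron genes had 2 higher and 7 lower adjusted over the list alone (limma camera adjusted p = 0.00119, and 0.0728 with an estimated correlation). The call of NRAMP1 ended when only the 6 libraries compared were fitted, and that of IRO3 (log2 fold change -0.95) ended when WT shoot replicate 1, 2 or 3 or spx4 shoot replicate 1 or 2 was left out. Pi starvation markers were not raised, with 1 of 14 called (1 adjusted over the list alone, limma camera adjusted p = 0.579, list median 0.03, and -0.08 with TPM). This was SPX2, lower (6.95 ± 0.774 against 11.2 ± 0.598 FPKM; SD, n = 3, limma adjusted p = 0.0401), a call that ended when any 1 of the 6 libraries was left out. Calls by limma were 0 of 8 defence markers, 0 of 12 phytoalexin genes and 0 of 8 jasmonate genes (2 higher and 1 lower adjusted over the list alone for the last), with 3085 genes at an unadjusted p under 0.05 over the tissue.

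Many of the genes that changed most in spx4 shoots were again near on or off. The EARLY FLOWERING 4 gene was at 0 reads in WT shoots and at 73.8 ± 7.13 FPKM in spx4 (SD, n = 3), at least 326-fold higher. An unannotated transcript on chromosome 4 with a DUF834 domain was at least 1080-fold higher, and a reverse transcriptase gene (LOC_Os01g03830) at least 310-fold higher, all against a floor of 3 reads over the group. A rhodanese-domain gene (LOC_Os04g17660) rose from 3.29 ± 0.665 to 151 ± 25.5 FPKM and the nitrite/sulphite reductase gene LOC_Os02g52730 from 0.381 ± 0.0575 to 30.4 ± 2.57 (SD, n = 3, limma adjusted p = 4.11e-09 and 1.56e-08). On the other side, 2 wall-associated receptor kinases (LOC_Os04g29810 and LOC_Os04g29790) were at 0 reads in spx4, at least 162-fold and 63.6-fold lower. The peptidase LOC_Os04g03796 fell from 62.9 ± 12.7 to 0.0251 ± 0.0304 FPKM (SD, n = 3, limma adjusted p = 6.91e-08). An NB-ARC resistance-type gene (LOC_Os11g12340), a cytochrome P450 (LOC_Os07g11739) and an O-methyltransferase (LOC_Os04g09604) fell with log2 fold changes of -4.34, -3.52 and -3.28. The transferase LOC_Os06g48560 lost its call without WT shoot replicate 1 or 2 or any spx4 replicate, a kinase (LOC_Os04g29770) was at least 197-fold lower, and 4 of the 20 genes carry a domain name only. The spx4 shoots had 428 of 19990 genes called by limma, 145 higher and 283 lower (33.9% higher, 22.8% with TPM), with 216 changed at least 2-fold. The count was 254, 274 and 277 without WT shoot replicate 1, 2 and 3, and 990 without WT low Pi shoot replicate 1, a library outside the comparison that shares its estimate of spread.

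The response of WT shoots to Pi shortage was read the same way. All 14 tested Pi starvation markers rose (14 adjusted over the list alone, limma camera adjusted p = 3.64e-15), and this list too passed with an estimated correlation (adjusted p = 0.048). IPS1 rose from 0.303 ± 0.471 to 275 ± 121 FPKM, SPX5 from 0.366 ± 0.206 to 222 ± 82.7 and the phospholipid-degrading enzyme GDPD2 from 2.3 ± 0.34 to 328 ± 69.4 (SD, n = 3, limma adjusted p = 2.89e-08, 1.77e-09 and 8.36e-10). The diacylglycerol glucosyltransferase gene LOC_Os08g20420 rose from 0.0237 ± 0.0247 to 121 ± 19.5 FPKM and an inorganic pyrophosphatase gene (LOC_Os05g02310) from 5.69 ± 1.56 to 222 ± 72.8 (SD, n = 3, limma adjusted p = 3.59e-11 and 3.86e-08). PECP1, the lipase LOC_Os11g43760 and a phosphoesterase (LOC_Os03g13540) rose with log2 fold changes of 5.06, 5.8 and 4.79. All 3 PHT1 genes tested rose, PT8 from 29.6 ± 2.93 to 228 ± 40.2 FPKM (SD, n = 3, 3 adjusted over the list alone, limma camera adjusted p = 0.00148, and 0.12 with an estimated correlation). Purple acid phosphatases were higher in 11 and lower in 1 of 13 cases, SPX domain proteins in 7 and 1 of 11, and both membrane lipid remodelling genes rose. The acid phosphatases had 11 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 1.16e-06, and 0.0924 with an estimated correlation). The SPX domain proteins had 8 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 4.38e-05, and 0.142 with an estimated correlation). Among regulators PHR4 rose from 7.77 ± 0.641 to 158 ± 20.7 FPKM (SD, n = 3, limma adjusted p = 3.4e-09). Its list had 3 higher and 5 lower of 14 (4 and 5 adjusted over the list alone, limma camera adjusted p = 0.91; median 0.01, and -0.03 with quantile normalization).

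Among jasmonate and defence genes of low Pi shoots, more were called higher than lower. The jasmonate synthesis genes AOS1, OPR7 and AOC rose from 8.96 ± 0.629 to 26.6 ± 5.12, from 22.4 ± 0.589 to 54.4 ± 8.09 and from 28.6 ± 1.64 to 63.8 ± 5.52 FPKM (SD, n = 3, limma adjusted p = 1.63e-05, 2.33e-06 and 1.56e-06). In that list 5 were higher and 1 lower of 8, and the lower gene was the jasmonate receptor COI1b. The jasmonate genes had 5 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 0.00927, and 0.197 with an estimated correlation). Lipoxygenases were higher in 8 of 10 cases, with LOC_Os12g37260 at 501 ± 304 against 49.2 ± 32.6 FPKM (SD, n = 3). The lipoxygenases had 8 higher and 0 lower adjusted over the list alone (limma camera adjusted p = 0.00148, and 0.0718 with an estimated correlation). Zim domain proteins, among them the JAZ repressors of jasmonate signalling, were higher in 8 and lower in 1 of 13 cases, LOC_Os03g08320 from 5.76 ± 1.62 to 62.5 ± 15.3 FPKM (SD, n = 3). The Zim domain proteins had 8 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 0.00148, and 0.232 with an estimated correlation). WRKY factors were higher in 39 and lower in 4 of 61 cases, and the defence markers in 5 and 0 of 8. The WRKY factors had 39 higher and 4 lower adjusted over the list alone (limma camera adjusted p = 7.14e-07, and 0.0502 with an estimated correlation). The defence markers had 5 higher and 0 lower adjusted over the list alone (limma camera adjusted p = 0.00337, and 0.232 with an estimated correlation). WRKY76 rose from 6.52 ± 1.9 to 97.8 ± 11.1 FPKM and WRKY45 from 42.1 ± 4.65 to 242 ± 8.96 (SD, n = 3, limma adjusted p = 4.91e-06 and 7.41e-07), whereas PR1b was not called, at 6.96 against 5.17 FPKM. In WT low Pi shoot replicate 1 the defence markers lay higher than in replicates 2 and 3, by a median of 0.84 on the log2 scale, and 4 of 8 by at least 2-fold.

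Chitinases were higher in 12 of 18 cases in low Pi shoots, with LOC_Os08g41100 at 20.6 ± 7.4 against 3.7 ± 0.726 FPKM (SD, n = 3). The chitinases had 12 higher and 0 lower adjusted over the list alone (limma camera adjusted p = 5.98e-05, and 0.142 with an estimated correlation). Class III peroxidases were higher in 23 and lower in 6 of 55 cases, with LOC_Os05g04380 at 16.4 ± 2.16 against 1.09 ± 0.351 FPKM (SD, n = 3). The class III peroxidases had 23 higher and 6 lower adjusted over the list alone (limma camera adjusted p = 0.0037, and 0.142 with an estimated correlation). Phytoalexin genes were called in 3 of 12 cases, all higher (3 adjusted over the list alone, limma camera adjusted p = 0.158), CPS2 and CYP701A8 with log2 fold changes of 2.11 and 1.98. Ribosomal proteins were lower in 146 and higher in 3 of 207 cases, the opposite of bHLH6-OV shoots, and those annotated as cytosolic in 4 of 5. The ribosomal proteins had 4 higher and 150 lower adjusted over the list alone (limma camera adjusted p = 9.67e-14, and 0.232 with an estimated correlation). The cytosolic ribosomal proteins had 0 higher and 4 lower adjusted over the list alone (limma camera adjusted p = 0.0222, and 0.373 with an estimated correlation). LOC_Os02g51790 of this group fell from 40.3 ± 5.51 to 5.57 ± 2.25 FPKM (SD, n = 3, limma adjusted p = 2.29e-06). Photosynthesis genes were lower in 7 of 26 cases and higher in 0, with LOC_Os04g44200 at 6.65 ± 2.05 against 16.1 ± 1.26 FPKM (SD, n = 3). This list was lower in replicate 1 than in replicates 2 and 3, by a median of -1.36 on the log2 scale. The photosynthesis genes had 0 higher and 7 lower adjusted over the list alone (limma camera adjusted p = 0.0328, and 0.654 with an estimated correlation).

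The iron list in low Pi shoots had 8 lower and 3 higher of 11 genes. The iron genes had 3 higher and 8 lower adjusted over the list alone (limma camera adjusted p = 0.0448, and 0.142 with an estimated correlation). NRAMP1 fell from 86.6 ± 22.8 to 0.436 ± 0.107 FPKM, IRO2 from 23.3 ± 4.49 to 0.205 ± 0.0963 and NAAT1 from 179 ± 65.1 to 14.6 ± 12.4 (SD, n = 3, limma adjusted p = 2.79e-06, 2.63e-08 and 0.00189). FER2 rose from 22.9 ± 3.93 to 72.9 ± 1.2 FPKM (SD, n = 3, limma adjusted p = 0.000732). A second zinc/iron permease (LOC_Os06g37010) fell from 55.7 ± 19.3 to 4.94 ± 3.89 FPKM, a family 17 glycoside hydrolase (LOC_Os05g31140) from 83.4 ± 11.7 to 4.93 ± 2.7 and a methyltransferase (LOC_Os05g47540) from 70 ± 11.3 to 4.88 ± 2.4 (SD, n = 3, limma adjusted p = 0.00123, 5.77e-06 and 2.42e-06). A prolyl oligopeptidase-type gene (LOC_Os04g47360) fell with a log2 fold change of -5.16, at 61.4 FPKM in low Pi replicate 1 and 5.86 and 5.18 in replicates 2 and 3. The nitrogen list gave 2 higher and 3 lower of 12 (2 and 3 adjusted over the list alone, limma camera adjusted p = 0.501), and 5 of the 20 genes chosen by size carry a domain name only. In all, limma called 9634 of 19990 genes, 4441 higher and 5193 lower (46.1% higher, 58.3% with TPM), with 2639 changed at least 2-fold, and 9462 without WT low Pi shoot replicate 1.

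Against bHLH6-OV shoots, spx4 shoots held less of most defence markers. PR1b stood at 1.15 ± 1.73 FPKM in spx4 and 417 ± 85.6 in bHLH6-OV (SD, n = 3, limma adjusted p = 2.99e-05). A barwin-domain gene (LOC_Os11g37950), of the PR4 type, stood at 0.963 ± 0.978 and 39.1 ± 20.3 (SD, n = 3, limma adjusted p = 9.5e-05). All 12 phytoalexin genes were lower in spx4, 7 of 8 defence markers and 7 of 18 chitinases, with 1 higher. The phytoalexin genes had 0 higher and 12 lower adjusted over the list alone (limma camera adjusted p = 2.39e-11, and 0.238 with an estimated correlation). The defence markers had 0 higher and 7 lower adjusted over the list alone (limma camera adjusted p = 7.8e-07, and 0.238 with an estimated correlation). The chitinases had 1 higher and 7 lower adjusted over the list alone (limma camera adjusted p = 0.00283, and 0.516 with an estimated correlation). WRKY factors were lower in 23 and higher in 10 of 61 cases and ribosomal proteins in 13 and 8 of 207. The WRKY factors had 11 higher and 26 lower adjusted over the list alone (limma camera adjusted p = 0.00595, and 0.345 with an estimated correlation). The ribosomal proteins had 0 higher and 4 lower adjusted over the list alone (limma camera adjusted p = 0.000335, and 0.598 with an estimated correlation). Pi starvation markers were higher in spx4 in 6 of 14 cases, with SPX2 at 6.95 ± 0.774 against 0.793 ± 0.229 FPKM and SPX-MFS2 at 36.6 ± 8.38 against 14.6 ± 1.09 (SD, n = 3, limma adjusted p = 8.13e-07 and 9.9e-05). The Pi starvation markers had 6 higher and 0 lower adjusted over the list alone (limma camera adjusted p = 0.028, and 0.598 with an estimated correlation). NRAMP1 and IRO2 were higher in spx4 than in bHLH6-OV (log2 fold changes 2.57 and 2.1). The iron list passed no camera test (5 higher and 3 lower of 11, 5 and 4 adjusted over the list alone, limma adjusted p = 0.41; median 0.14, and -0.2 with TPM). The bHLH6 gene itself was lower in spx4 (log2 fold change -2.2, limma adjusted p = 0.0224), a call that ended without bHLH6-OV shoot replicate 2 or 3 or spx4 shoot replicate 1. SPX4 was lower as well (-0.37, limma adjusted p = 0.0305), and its call ended without bHLH6-OV shoot replicate 2 or 3 or spx4 shoot replicate 2 or 3. Among the genes chosen by size, a cytochrome P450 (LOC_Os02g47470) stood higher in spx4, at 48.9 ± 5.93 against 3.53 ± 1.22 FPKM (SD, n = 3). So did the aminotransferase LOC_Os01g09700 and the glycoside hydrolase LOC_Os01g59840 (log2 fold changes 3.39 and 3.28), while the cytochrome P450 LOC_Os07g11739 and the chitinase LOC_Os10g39680 stood lower (-5.83 and -5.42). In all, limma called 6403 of 19990 genes, 3652 higher and 2751 lower in spx4 (57% higher), and 4027 without bHLH6-OV shoot replicate 1. The higher share was 41.1% with median ratio scaling and 14.5% with TPM, which moved the median log2 fold change of all genes from 0.06 to -0.24.

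**Figure D3:**
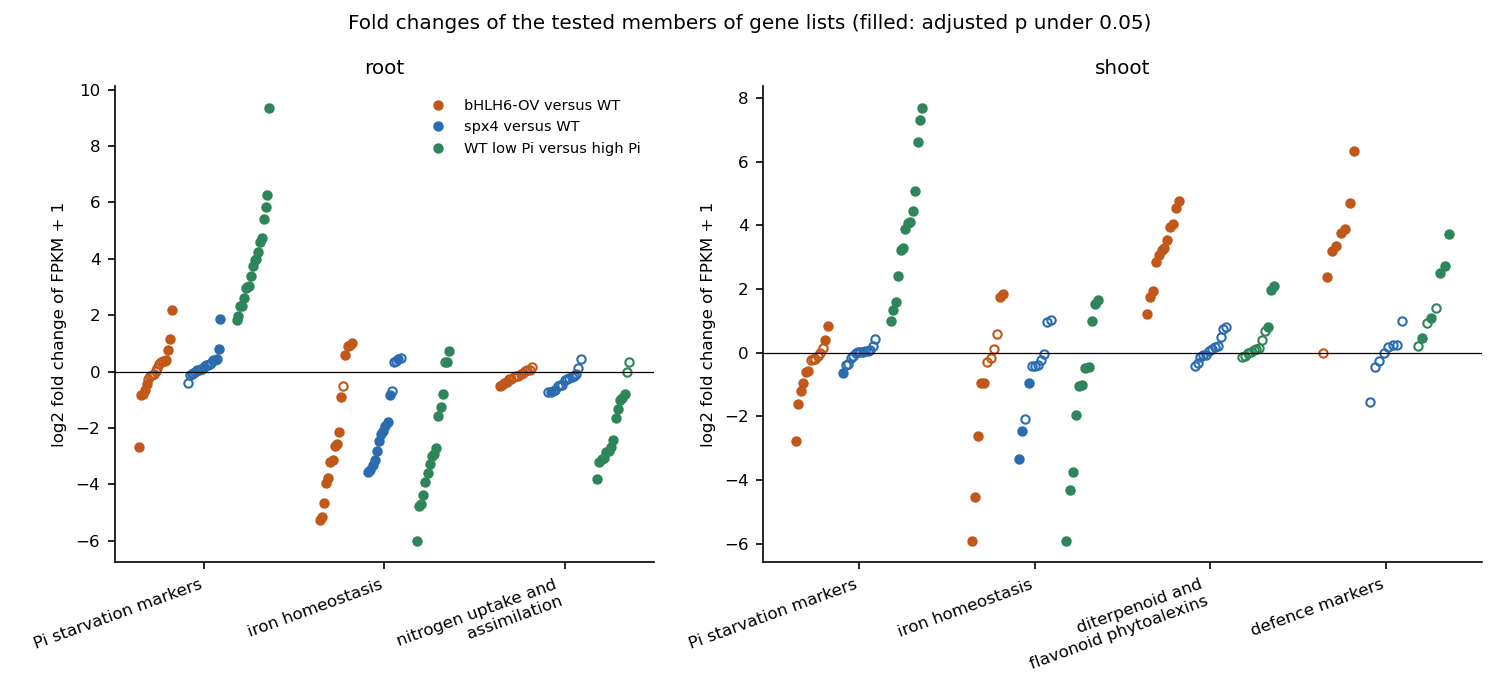
Log2 fold changes of FPKM + 1 for the tested members of fixed gene lists in roots (left) and shoots (right), with 1 point per gene, filled where called by limma. All Pi starvation markers lie above 0 at low Pi, most iron genes of roots lie below 0 in the 3 comparisons, and phytoalexin genes and defence markers of shoots lie mostly above 0 in bHLH6-OV.

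Calls shared between the comparisons were counted within each tissue. In roots bHLH6-OV and spx4 had 69 genes higher in both and 237 lower in both, against 11 and 42 for independent lists, with 16 of opposite direction. The iron genes were part of this: 11 of 16 were lower in bHLH6-OV, in spx4 and at low Pi alike, among 106 root genes lower in all 3, and in shoots 3 of 11, among 77. Unchanged groups simulated against the same WT libraries shared at most 1 call of the same direction in 100 draws and 0 iron genes. In shoots bHLH6-OV and WT low Pi shared 1241 higher and 1606 lower calls, against 622 and 900 for independent lists, with 849 of opposite direction, while in roots they shared 207 and 430, against 258 and 369, with 1166 of opposite direction. The covariance of the log2 fold changes of bHLH6-OV and spx4 exceeded the simulated one by 0.06 in roots and 0.057 in shoots, that of bHLH6-OV and low Pi by 0.143 in shoots and by -0.017 in roots. For spx4 and low Pi the excess was 0.002 in roots, with 25 shared higher and 151 shared lower calls against 21 and 65, and 0.049 in shoots, with 67 and 143 against 32 and 74. In shoots bHLH6-OV and spx4 shared 73 and 127 against 20 and 49. All 3 comparisons share the WT high Pi libraries, from which part of any excess may come.

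Effects in roots and shoots of a line or treatment were tested for a difference. bHLH6-OV effects differed most in phytoalexin genes (11 of 12 lower in roots, limma camera adjusted p = 9.13e-12, and 0.0826 with an estimated correlation). Next were defence markers (7 of 8, limma camera adjusted p = 1.66e-07, and 0.0826 with an estimated correlation). Only 5 phytoalexin genes passed the root filter, so low root levels may play a part. PR1b stood at 0.0721 FPKM in roots of both bHLH6-OV and WT, and root minus shoot was -6.34 (log2, limma adjusted p = 2.15e-05). At low Pi the nitrogen genes had a lower effect in roots in 11 of 16 cases (limma camera adjusted p = 9.28e-08, and 0.183 with an estimated correlation). Ribosomal proteins had a higher effect in roots in 115 of 208 (limma camera adjusted p = 7.33e-13, and 0.425 with an estimated correlation). NAS1 and NAS2 are root genes here, at 0 and 0.0424 FPKM in WT shoots. In limma the effect differed between the tissues for 6751 of 22980 genes in bHLH6-OV, 420 in spx4 and 8707 at low Pi. Genes called in both tissues moved the same way in 318 higher and 349 lower cases in bHLH6-OV (174 and 259 for independent lists) and in opposite ways in 419. At low Pi 1211 and 1074 moved the same way (554 and 693) and 668 in opposite ways, and in spx4 34 and 89 (1 and 3) and 0 in opposite ways, of 17437 genes tested in both tissues.

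The near on or off genes of spx4 were counted by position. A gene was taken as on with at least 1 FPKM in all 3 libraries of a group and as off below 0.1 in all 3. The spx4 roots had 44 genes on that were off in WT and 49 off that were on in WT, bHLH6-OV roots 114 and 2, and low Pi roots 15 and 2. In spx4 shoots the numbers were 39 and 51. The root genes of spx4 gathered on chromosome 4 (34 of 93, with 16 each on 7 and 11), 17 in its first 5 Mb. In 10000 permutations over expressed positions any such window held at most 11 (p = 1e-04, the smallest possible). In the first 20 Mb of chromosome 4, 54 of 544 tested root genes (9.9%) changed at least 2-fold in spx4, against 0.8% elsewhere, and 53 of 516 shoot genes (10.3%) against 0.84%. SPX4 itself lies on chromosome 3.

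**Figure D4:**
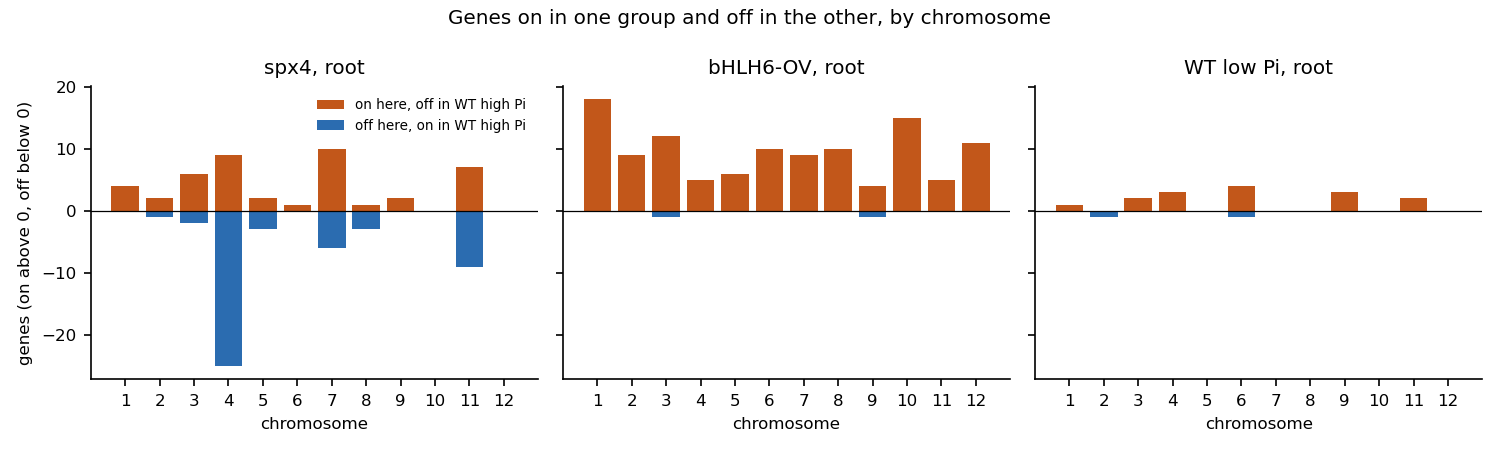
Number of root genes on in a group and off in WT at high Pi (above 0) or off in the group and on in WT (below 0), on each of the 12 chromosomes. In spx4 34 of 93 lie on chromosome 4 and 16 each on 7 and 11, while those of bHLH6-OV spread over all.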

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

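The results here are those where root and shoot differed in a test of the difference itself, whose form was fixed before the data were examined. Values are root effect minus shoot effect on the log2 scale, from limma. The effect differed for 6751 genes in bHLH6-OV, 420 in spx4 and 8707 at low Pi. Of 100 drawn splits of the 12 libraries, 1, the real one, called as many in each. The splits regrouped root and shoot libraries separately, so they stand for no effect in either tissue. They cannot show whether the difference between the tissues arose by chance. The highest other split called 6458, 213 and 7291 genes, and how these splits grouped the libraries was not recorded.

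In bHLH6-OV roots, phytoalexin genes (median -3.56, 5 tested there), defence markers (-4.04), iron genes (-0.86), chitinases (-0.35) and ribosomal proteins (-0.37) lay lower. Photosynthesis genes lay higher there (1.45). In spx4, Pi starvation markers lay higher in roots (0.19) and iron (-0.71) and nitrogen genes (-0.48) lower. At low Pi, PHT1 transporters (1.97), cytosolic ribosomal proteins (0.66), ribosomal proteins (0.53) and Pi starvation markers (0.47) lay higher in roots, and nitrogen (-2.06), defence (-1.35), iron (-1.24), chitinases (-0.9), root tissue markers (-0.71) and WRKY factors (-0.68) lower. With an estimated correlation no list of the 19 passed by limma's camera, the lowest adjusted p being 0.0826.

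Single genes with the highest differences in bHLH6-OV were the carboxyl methyltransferase LOC_Os11g15040 (4.56), the phytocyanin LOC_Os08g37660 (4.4), the aminotransferase LOC_Os01g09700 (4.32), the DNA-binding protein LOC_Os09g35010 (4.31) and the cytochrome P450 LOC_Os02g47470 (4.15). The lowest were PR1b (-6.34), the oligopeptide transporter LOC_Os01g65110 (-6.13), the chitinase LOC_Os10g39680 (-5.61), NAS2 (-5.31) and NAS1 (-5.18). LOC_Os01g65110 stood at 0.64 FPKM in bHLH6-OV and 12.9 in WT roots, but 12.5 and 0.42 in shoots.

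In spx4 the highest were the wall-associated kinases LOC_Os04g29810 (4.55) and LOC_Os04g29790 (3.63), the kinase LOC_Os04g29770 (4.49), the dehydrogenase LOC_Os04g02620 (3.58) and the cytochrome P450 LOC_Os07g11739 (3.46), none of which reached 1 FPKM in roots. The lowest were an unannotated transcript on chromosome 4 with a DUF834 domain (-5.86), the rhodanese LOC_Os04g17660 (-5.14), the lectin LOC_Os04g03579 (-3.92), the metallothionein LOC_Os12g38270 (-3.61) and NAS1 (-3.58).

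At low Pi the highest were LOC_Os03g31750 of the pyruvate kinase type (4.91), PT6 (4.72), the prolyl oligopeptidase LOC_Os04g47360 (4.01), the multicopper oxidase LOC_Os01g03640 (3.94) and PT3 (3.75). The lowest were the molybdopterin oxidoreductase LOC_Os02g53130 (-7.38), YSL15 (-6.07), the cytochrome P450 LOC_Os06g43410 (-5.02), NAS2 (-4.96) and NAS1 (-4.87). LOC_Os02g53130 stood at 1.55 FPKM at low and 44 at high Pi in roots, and at 71.5 and 6.48 in shoots.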

How the results depend on the processing

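All alternatives but 4 were chosen before the data were examined; the 4 added after are named as such. Counts are genes called by limma.

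Asking for at least 2-fold left 646, 227, 1182 and 385 root calls (bHLH6-OV, spx4, low Pi, spx4 against bHLH6-OV) and 1463, 216, 2639 and 1426 shoot calls. Shared calls in the same direction fell from 306 to 87 (bHLH6-OV and spx4), 637 to 109 (bHLH6-OV and low Pi) and 176 to 67 (spx4 and low Pi) in roots, and from 200 to 70, 2847 to 428 and 210 to 62 in shoots.

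A stricter filter gave 297 calls in spx4 roots and 255 in spx4 shoots, and 842 for spx4 against bHLH6-OV in roots. A fit of only the 6 libraries compared gave 746 in spx4 shoots and 889 for spx4 against bHLH6-OV in roots. With arrayWeights, whose estimate did not converge, the root counts were 6405, 5306, 14172 and 5974, and shoots of bHLH6-OV and spx4 had 9425 and 861; the log2 fold change of bHLH6 in low Pi roots, not called at 0.31, became -1.2 and was called. Without genes on in 1 of spx4 and WT and off in the other, an alternative added after the data were examined, spx4 had 428 calls in roots and 329 in shoots.

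With each library of the 2 groups compared left out in turn, the root counts ran from 2156 to 3408 (bHLH6-OV), 331 to 542 (spx4), 4919 to 7377 (low Pi) and 815 to 1962 (spx4 against bHLH6-OV). In shoots they ran from 4401 to 7789, 254 to 990, 7987 to 9462 and 4027 to 8156. The highest count of spx4 shoots, 990, came without WT low Pi shoot replicate 1, the one library outside a comparison that was left out (another added), as did 7789 and 8156. The root minus shoot counts ran from 5416 to 6521, 286 to 549 and 7588 to 8719.

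Replicate numbers may pair the libraries of bHLH6-OV and spx4 roots by the check on residuals. A replicate block in these 2 groups only, also added, gave 2101 calls between them against 1454, and under it camera passed the jasmonate list and kept its other list calls, while more members of several lists were called. Elsewhere at least 1 same-numbered pair did not correlate above 0.1, so samples share only a number (median 0.02 over root groups and 0.02 over shoot groups, and -0.03 to 0.13 between root and shoot of 1 group). All 6 libraries correlated best with their own number between WT and bHLH6-OV in roots and in shoots, and between root and shoot of WT at high Pi and of spx4, a hint from the data and not the design. With the replicate block over all groups the counts were 3813, 493, 6649 and 1349 in roots, 5891, 399, 9327 and 6104 in shoots, and 6293, 300 and 8250 for root minus shoot.

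For 566 results of named genes (291 genes), 9825 values were the same over the alternatives, 509 weaker (346 of them with a library left out), 12 stronger and 1 reversed. Of 59 list calls by camera, 57 were lost with an estimated correlation; the Pi starvation markers at low Pi passed in both tissues. Without bHLH6 and SPX4 in the lists, also added, 3 list calls were lost: the Pi signalling regulators in bHLH6-OV roots (0.0511) and between spx4 and bHLH6-OV roots (0.158), and the SPX domain proteins in bHLH6-OV shoots (0.0742).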

Other observations

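Gene families with at least 10 tested members were scanned after the results were seen, 214 in roots and 195 in shoots. Given is the family of lowest limma camera adjusted p per comparison outside the report's lists, then its adjusted p with an estimated correlation. In bHLH6-OV roots it was the major intrinsic proteins (0 higher and 9 lower of 17, 0.000293 and 0.799), which the aquaporin list does not hold. In low Pi roots 2 of them were higher and 11 lower (0.000562 and 0.971). There it was the zinc/iron permeases (0 higher and 10 lower of 16, 0.000332 and 0.971), in spx4 roots UDP-glucosyltransferases (0 and 4 of 85, 2.31e-05 and 0.803). In shoots it was proteasome subunits in bHLH6-OV (11 and 0 of 22, 0.000203 and 0.936), wall-associated kinases in spx4 (0 and 3 of 16, 0.00165 and 0.986) and family 61 glycosyltransferases at low Pi (14 and 0 of 17, 5.44e-05 and 0.25).

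Of the tests of explanations below, the excess of root genes in a shoot library and the comparison of iron genes between spx4 and bHLH6-OV were chosen after the results were seen, and the others before their values were known.

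The iron list lay lower in roots of bHLH6-OV, spx4 and WT at low Pi than in WT at high Pi. Scaling would have moved at least 1 of the 3 list medians above -0.5. The highest after median ratio scaling was -2.01, which argues against scaling. Simulated unchanged groups shared at most 1 call, so their 0 iron genes lower in all 3 cannot test chance in WT. Between spx4 and bHLH6-OV roots 3 of 16 list members were called (5 higher and 3 lower adjusted over the list alone), and WT at low Pi is not in that comparison, so it does not show whether the 3 groups are alike. A state of the WT high Pi plants apart from Pi and genotype may still lie behind the pattern: all 3 groups are set against the same WT plants, so these data cannot tell that state from an effect common to the groups. New WT plants would be a test.

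Genes on in 1 of spx4 and WT and off in the other may, as a hypothesis, come from sequence differences of the spx4 line that have nothing to do with SPX4. Of the root genes of this kind expressed in shoots, 78.5% were on or off the same way there, but so were 65.1% of those of bHLH6-OV, so this is not particular to spx4. Of the root genes only those of spx4 gathered, densest at the start of chromosome 4 (permutation p = 1e-04, the smallest possible). The p was 0.583 in bHLH6-OV and 0.14 at low Pi. The 1 FPKM cut largely keeps the lowest read number (median 120) over the bound of 10, so it cannot test too few reads. A second spx4 allele would be a test.

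WT low Pi shoot replicate 1 stood apart from replicates 2 and 3. After median ratio scaling 418 genes were still at least 2-fold higher, the smaller of the 2 directions, which argues against scaling. Root tissue could be in the library: root genes stood at 2.8% of their low Pi root level, but at 2.06 and 2.42% in replicates 2 and 3, so the bound set beforehand did not separate them. The excess of 0.56% is too small to lower photosynthesis genes by a median of -1.36 on the log2 scale. Clock genes differed by 0.29 (median), under the 0.3 bound set against another harvest time but too near to decide. All 7, of dawn, day and evening, were lower in replicate 1.

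For each comparison within a tissue, 1 of the 10 splits of its 6 libraries, the real one, called as many genes, and 10 splits are too few for a share under 0.05. The real counts by limma were 3975, 543, 6941 and 1454 in roots, where the highest other split called 0, 0, 1 and 1, and 6266, 428, 9634 and 6403 in shoots, where it called 0.

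Of genes on in bHLH6-OV and off in WT roots (114) and in spx4 (44), 12 were shared (both sets use the same WT libraries), and 10 of these were below 0.1 FPKM in all WT low Pi root libraries.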
